A study of Solanum lycopersicum with 24 samples.

How the data were processed

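Hairy roots are root cultures that grow from tissue transformed with Rhizobium rhizogenes, and here they came from the tomato cultivar M82. Per the labels' protocols, roots were kept for 9 days in the dark at 25 °C on medium with 3% sucrose, and the first 1 cm of 10 root tips was pooled for each sample. RNA was bound through its poly(A) tail, and libraries were made with random primers without marking the strand and sequenced as paired reads of 75 bp. The labels give 8 groups of 3 samples: an empty-vector control, SlMYB41, SlMYB92 and SlWRKY71 overexpression from the 35S promoter as fusions with a FLAG tag, CRISPR/Cas9 knockouts of SlMYB41 and SlMYB92, and knockout lines 4 and 5 of SlWRKY71. The protocol speaks of 4 biological replicates per line, while 3 libraries per group were analysed here. The labels name a line for each group and no second line of the same kind except for the SlWRKY71 knockout, so that a difference between groups includes any difference between individual hairy root lines. The p-values measure the spread between samples within these groups.

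The deposited table holds estimated counts per transcript for 24 libraries, which the authors made with Trim Galore 0.6.6 and kallisto 0.46.2, per the submitters' processing notes. The transcript annotation is not given in the sources used here. Of the values, 6.18% were not whole numbers at a tolerance of 1e-09, and the estimated counts were rounded before testing. Pseudoalignment shares reads between near-identical copies by estimation, so values of genes with close paralogs, such as the phenylalanine ammonia-lyase copies, are uncertain. Because strand was not marked, overlapping genes on opposite strands cannot be separated. Reads from a transgene count towards the locus of the same coding sequence, so a rise of an overexpressed gene does not separate transgene from native transcript. Reads of an edited gene can still be counted, so the count of a knocked-out gene need not fall. Each column was assigned to a group by its name. The numbers in the column names run from 2 to 5 and are not the replicate numbers of the labels, so libraries are named here by the number in the column.

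The table lists 34688 transcripts, 1 per locus, of which 6566 had no count. Library totals ran from 4852464 to 15372241 estimated counts. A filter on expression (filterByExpr) left 18297 genes. Libraries were scaled by TMM, with factors from 0.909 to 1.12, and all 24 libraries entered 1 edgeR quasi-likelihood fit (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with a mean per group, so that all groups share the estimate of the spread. The common dispersion was 0.0789, a biological coefficient of variation of 28.1%. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. There were 12 comparisons: 7 of a group with the control and 5 directly between groups. CPM values are scaled by TMM. Standard errors of log2 fold changes were taken as the size of the change divided by the square root of its F statistic. Where a group had no count for a gene, the fold is a bound against a floor of 3 counts over the group. With 1 to 3 counts it is a ratio with a 95% counting interval, and these bounds and intervals cover counting error only. In data simulated after SlMYB41 overexpression against control, with 17432 genes, the test found 32 of 100 genes changed 2-fold and 80 of 100 changed 4-fold, with 8 false calls. Only genes above 2 CPM were changed in this simulation. Most of the named loci lie lower in the control, and the shares found do not hold for them.

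The sources used here do not pair the identifiers with gene names: 0 of 34688 identifiers were found in the reference table. Before the data were examined, 13 loci that are reported on here were written down with their symbols from memory, and these names were checked against no table. Of them, 1 locus, a second phenylalanine ammonia-lyase copy, is not analysed here, 2 were below the filter and 10 were tested. A further locus written down at that time was left out after the tests had been seen, so the counts adjusted over the list alone rest on a list shortened at that point. This gave passes over the list alone that the longer list did not, in the SlMYB92 knockout and between SlMYB41 overexpression and knockout. Names of further loci recalled after the data had been seen were left out. The other part of the rule for named genes, also set before the data were examined, asked for a product name. Without product names, at most 2 identifiers that rose and 2 that fell are given per comparison: the largest log2 fold changes among called genes whose libraries did not overlap in CPM, which 3 libraries against 3 reach by chance in 10% of genes. For the same reason the 28 gene lists fixed beforehand, including lists for other cell types, could not be filled. The largest held 4 tested loci, below the minimum of 5, and no list was tested.

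Replicates of each group were compared in pairs. No 2 libraries were identical, chi-square values per degree of freedom ran from 6.53 to 44.2, and Spearman correlations across genes from 0.919 to 0.981, so every library was counted once. Comparisons with the same control share its chance variation. For pairs of such comparisons, 10 simulations were run of unchanged groups that share a control of 3 libraries. The overlap of independent lists was also computed. Where no group is changed few genes are called, so the simulated counts of shared calls were nearly fixed in advance. They cannot show how much overlap comes from the control, such as from traits of the control line. The simulated covariance and correlation cover its chance variation only. The 3 control libraries cannot be divided into parts of at least 2. The alternatives tried were RLE scaling, no filter and a stricter filter, DESeq2 1.42.0, a fit of only the groups compared, a robust fit, a test against a log2 fold change of 1 (glmTreat), and leaving out each library in turn. After the data had been seen, 4 more were added: the overlaps of SlWRKY71 overexpression with its knockout lines without each of its libraries, a replicate block by the number in the column, the mean of the groups that target other genes as the reference in place of the control, and counts without a segment of chromosome 12 and without genes that changed against the control in all 7 comparisons.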

Results

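Transcript levels were measured in root tips of 8 kinds of tomato hairy root, with 3 libraries each and 4852464 to 15372241 estimated counts per library. The question in the series design is how knockout or overexpression of the exodermis-enriched transcription factor genes SlMYB41, SlMYB92 and SlWRKY71 changes the transcriptome. The exodermis is the outer cortical cell layer of the root, which in tomato deposits suberin, a polyester of fatty acids and phenolics. Of the loci named beforehand, 7 were tested beside the 3 targets. They were SlASFT (Solyc03g097500), a feruloyl transferase of suberin synthesis, the glycerol-3-phosphate acyltransferases SlGPAT4 (Solyc01g094700) and SlGPAT6 (Solyc09g014350), the fatty acid hydroxylase SlCYP86B1 (Solyc02g014730), the fatty acid elongase SlCER6 (Solyc02g085870), the cutin synthase SlCD1 (Solyc11g006250), and PAL5 (Solyc09g007920), a phenylalanine ammonia-lyase of the phenylpropanoid pathway.

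Each overexpressed gene had its highest group mean in its own group. SlMYB41 (Solyc02g079280) stood at 12.4, 13.6 and 7.18 CPM in libraries 2, 3 and 5 of its overexpression group and at 0, 0.159 and 0 CPM in the control libraries. SlMYB92 (Solyc05g051550) stood at 48.2, 87.6 and 60.6 CPM in libraries 2, 3 and 4 of its overexpression group, and its control libraries at 0, 0 and 0.188 CPM. SlWRKY71 (Solyc02g071130) stood at 5.21, 41.5 and 26.2 CPM in libraries 2, 4 and 5 of its overexpression group, against 1.99, 1.59 and 1.13 CPM in the control. SlMYB41 and SlMYB92 were too low in the control for a fall in their knockouts to be detectable at this depth. SlMYB41 had 0, 0 and 2 counts in the SlMYB41 knockout libraries, and SlMYB92 had 3, 0 and 0 counts in the SlMYB92 knockout libraries. SlWRKY71 was at 2.1 ± 1.05 CPM in knockout line 4 and 2.07 ± 1.99 CPM in line 5 (SD, n = 3), against 1.57 ± 0.432 CPM in the control. Its log2 fold changes were 0.39 (SE 0.77) and 0.35 (SE 0.79), with edgeR quasi-likelihood adjusted p of 0.79 and 0.82.

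**Figure D1:**
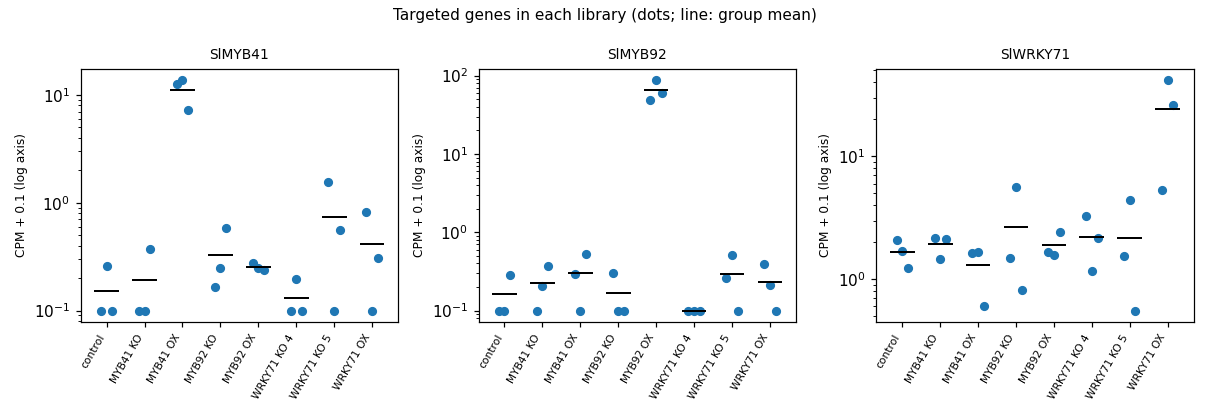
CPM plus 0.1, on a log axis, of the 3 targeted genes in each of the 24 libraries (dots), with the group mean as a line. SlMYB41 reaches 13.6 CPM, SlMYB92 87.6 CPM and SlWRKY71 41.5 CPM in their overexpression groups.

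With SlMYB92 overexpressed, 5 of the 7 tested loci rose against the control, none fell and 2 did not pass the test. The count was also 5 when adjusted over the list alone, the list being these 7 loci. SlASFT rose from 2.64 ± 1.45 to 160 ± 82.4 CPM (SD, n = 3), a log2 fold change of 5.97 (SE 0.76; edgeR quasi-likelihood adjusted p = 4.2e-05). SlGPAT4 rose from 1.92 ± 0.549 to 46.2 ± 24.6 CPM, a log2 fold change of 4.58 (SE 0.54; edgeR quasi-likelihood adjusted p = 1.3e-05). SlGPAT6, at 0 counts in the control, was at least 18.9-fold higher (edgeR quasi-likelihood adjusted p = 0.024). SlCYP86B1 rose by 4.84 on the log2 scale (SE 0.99), from 0.251 ± 0.338 to 6.52 ± 4.25 CPM, with an edgeR quasi-likelihood adjusted p of 0.0072. SlCER6, with 2 counts in the control and 65 with SlMYB92 overexpressed, had a ratio of 41.8 (counting interval 11.1 to 353; edgeR quasi-likelihood adjusted p = 0.0024). SlCD1 and PAL5 had log2 fold changes of -0.71 (SE 0.67) and -0.49 (SE 0.43), with edgeR quasi-likelihood adjusted p of 0.65 and 0.62. SlGPAT5 (Solyc04g011600) was below the filter, with 44 counts with SlMYB92 overexpressed and 10 in the control.

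SlMYB92 itself had a ratio of 845 to the control (counting interval 233 to 6980; edgeR quasi-likelihood adjusted p = 8e-08). In all, 370 genes rose and 231 fell. Solyc08g008540 and Solyc07g042335, with no count in the control, were at least 115-fold and 69.5-fold higher, and Solyc09g064273 and Solyc09g009560 at least 52.8-fold and 37.3-fold lower. With the groups that target other genes as reference, the 5 loci kept their calls, with log2 fold changes from 2.71 for SlCER6 to 5.72 for SlASFT. Of the 601 genes, 207 changed the same way there. Solyc08g008540, Solyc09g064273 and Solyc09g009560, at 0.64, -1.56 and -3.99 on the log2 scale, lost their calls, Solyc09g064273 also with DESeq2. That reference holds SlMYB41 overexpression, in which Solyc09g064273 and Solyc09g009560 also had no count. Solyc09g064273 was at 0 CPM in every group but the control, at 8.39 CPM, and SlWRKY71 overexpression, at 3.55 CPM. SlGPAT6 lost its call without any 1 control library (edgeR quasi-likelihood adjusted p of 0.072, 0.068 and 0.095 without libraries 2, 3 and 5) and without overexpression library 2 or 4 (0.083 and 0.065), and SlCYP86B1 without control library 5 (0.054). Tested against a log2 fold change of 1 with glmTreat, SlGPAT6 did not pass (edgeR quasi-likelihood adjusted p = 0.082). The count of genes was 963 with DESeq2, 139 with glmTreat, 314 without control library 3, 292 without control library 5, 292 without overexpression library 2 and 261 without overexpression library 4.

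**Figure D2:**
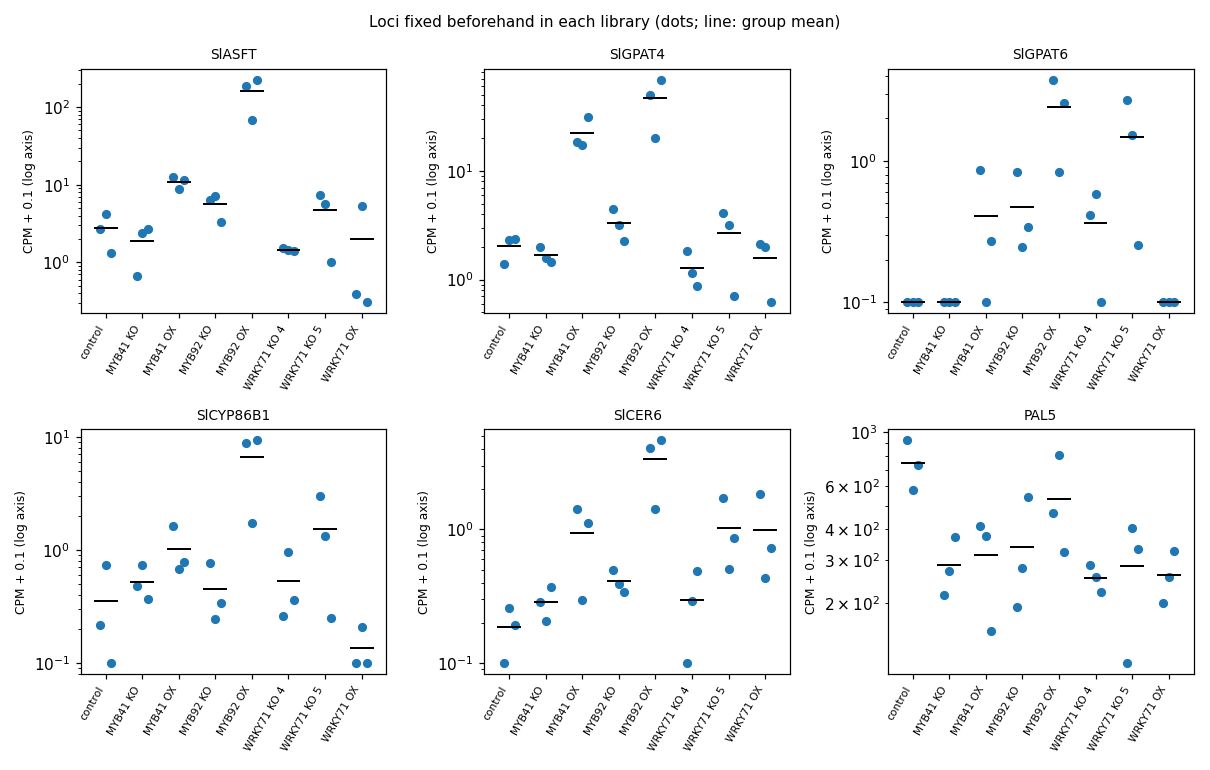
CPM plus 0.1, on log axes, of SlASFT, SlGPAT4, SlGPAT6, SlCYP86B1, SlCER6 and PAL5 in each library (dots), with group means as lines. The SlMYB92 overexpression means, 160 CPM for SlASFT and 46.2 CPM for SlGPAT4, lie above those of the other 7 groups, as they do for SlGPAT6, SlCYP86B1 and SlCER6, while PAL5 is highest in the control, at 744 CPM.

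With SlMYB41 overexpressed, 1 of the 7 loci rose, none fell and 6 did not pass the test, whereas 4 passed when adjusted over the list alone: SlGPAT4, SlCER6 and SlASFT above the control and PAL5 below it. SlGPAT4 rose from 1.92 ± 0.549 to 22.2 ± 7.65 CPM (SD, n = 3), a log2 fold change of 3.53 (SE 0.52; edgeR quasi-likelihood adjusted p = 0.00042). SlASFT was at 10.8 ± 1.88 CPM against 2.64 ± 1.45 CPM, a log2 fold change of 2.09 (SE 0.71) that did not pass over all genes (edgeR quasi-likelihood adjusted p = 0.25). SlCER6 had 20 counts against 2, SlCYP86B1 19 against 5 and SlGPAT6 6 against 0, with edgeR quasi-likelihood adjusted p of 0.17, 0.64 and 0.56. PAL5 was at 315 ± 141 CPM against 744 ± 172 CPM (log2 fold change -1.24, SE 0.44; edgeR quasi-likelihood adjusted p = 0.27).

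SlMYB41 itself had a ratio of 252 to the control (counting interval 44.8 to 10000; edgeR quasi-likelihood adjusted p = 0.00037). In all, 119 genes rose and 60 fell. Solyc08g008540 and Solyc01g060055 were at least 194-fold and 125-fold higher than in the control, and Solyc09g064273 and Solyc09g009560 at least 59.3-fold and 41.9-fold lower. Against the groups that target other genes SlGPAT4 kept its call with a log2 fold change of 2.61, and 43 of the 179 genes changed the same way. SlASFT, SlCYP86B1 and SlCER6 were at only 0.76, 0.54 and 0.28 there, PAL5 at -0.03, and SlGPAT6 turned to -0.27, with edgeR quasi-likelihood adjusted p of 0.89, 0.99, 1, 1 and 1. With that reference Solyc08g008540 was higher by only 1.70 and Solyc01g060055 by 5.96 on the log2 scale. It leaves out the SlMYB41 knockout, in which Solyc01g060055 was also high. That gene was at 14.7 CPM with SlMYB41 overexpressed, 10.6 CPM in the SlMYB41 knockout and 0 CPM in the control. Solyc09g064273 and Solyc09g009560, at -1.56 and -3.52, lost their calls, Solyc09g064273 also with DESeq2. The reference holds SlMYB92 overexpression, in which Solyc09g064273 and Solyc09g009560 also had no count. Outside the control and SlWRKY71 overexpression, at 8.39 and 3.55 CPM, Solyc09g064273 was at 0 CPM in every group. The count was 342 with DESeq2, 68 with glmTreat, 119 against the groups that target other genes, 108 without control library 3, 94 without control library 5, 106 without overexpression library 3 and 111 without overexpression library 5.

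Between these overexpression groups, SlASFT was higher with SlMYB92 than with SlMYB41 by 3.88 on the log2 scale (SE 0.67; edgeR quasi-likelihood adjusted p = 0.0052), and lost this call without SlMYB41 overexpression library 3 (adjusted p = 0.057). SlGPAT4 and SlCYP86B1 had log2 differences of 1.05 (SE 0.44) and 2.83 (SE 0.85), with edgeR quasi-likelihood adjusted p of 0.42 and 0.18, and SlCER6 and SlGPAT6 of 1.90 (SE 0.70) and 2.92 (SE 1.09), with 0.32 and 0.35. All 5 passed when adjusted over the list alone. Of all genes, 75 were higher and 26 lower with SlMYB92. Solyc11g042950 and Solyc01g065643 were at least 53.2-fold and 36-fold higher, and Solyc05g005865 and Solyc04g077750 at least 13.6-fold and 13.4-fold lower. Solyc01g065643 lost its call with DESeq2, with glmTreat, without any 1 SlMYB41 overexpression library or without SlMYB92 overexpression library 3, and Solyc05g005865 with glmTreat and in 6 of 6 fits without a library. The count of 101 was 237 with DESeq2, 24 with glmTreat, 44, 34 and 54 without SlMYB41 overexpression libraries 2, 3 and 5, and 51 and 55 without SlMYB92 overexpression libraries 2 and 4. Against the control, 88 genes were higher and 30 lower in both groups, where independent lists would share 2.41 and 0.758. Simulated unchanged groups shared 0 and 0, which was nearly fixed in advance. The covariance of the log2 fold changes was 0.42 against 0.09 simulated and their correlation 0.66 against 0.48, and part of the excess overlap may come from the shared controls.

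In the SlMYB41 knockout none of the 7 loci passed the test over all genes, and 2 did when adjusted over the list alone. SlCD1 was at 0.285 ± 0.0837 CPM against 1.68 ± 0.924 CPM in the control (SD, n = 3; log2 fold change -2.53, SE 0.78; edgeR quasi-likelihood adjusted p = 0.063). PAL5 was at 286 ± 78.4 CPM against 744 ± 172 CPM (log2 fold change -1.38, SE 0.44; edgeR quasi-likelihood adjusted p = 0.07). SlASFT and SlGPAT4 had log2 fold changes of -0.40 (SE 0.81) and -0.31 (SE 0.59), with edgeR quasi-likelihood adjusted p of 0.82 and 0.8. In all, 479 genes rose and 456 fell. Solyc09g005420 rose from 0.279 ± 0.267 to 348 ± 51.2 CPM, a log2 fold change of 10.22 (SE 0.92; edgeR quasi-likelihood adjusted p = 1.2e-07), and Solyc06g075675 and Solyc01g058673, with no count in the knockout, were at least 121-fold and 77.5-fold lower. Against the groups that target other genes Solyc06g075675 and Solyc01g058673 were at -4.72 and -7.24 on the log2 scale and did not pass. That reference holds the SlMYB92 knockout, in which Solyc01g058673 also had no count and Solyc09g005420 was also high, at 263 CPM. Solyc06g075675 was at 16.6 CPM in the control and lower in every other group, SlMYB41 overexpression included, at 0.374 CPM. Its highest mean outside the control was 3.91 CPM, in SlWRKY71 overexpression. SlCD1 passed with DESeq2 or without control library 2, and PAL5 with no filter, with DESeq2 or with only the groups compared. With the groups that target other genes as reference PAL5 was at -0.16, SlCD1 at -2.0, SlASFT at -1.73 and SlGPAT4 at -1.23 on the log2 scale, and none of them passed. The count of genes was 1453 with DESeq2, 232 with glmTreat, 556 against the groups that target other genes, 482 without control library 5 and 585 without knockout library 5, and 350 of the 935 genes changed the same way against the groups that target other genes.

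In the SlMYB92 knockout none of the 7 loci passed the test over all genes, and 3, SlCD1, PAL5 and SlGPAT6, did when adjusted over the list alone. All 3 of these passes depend on the list having been shortened after the tests had been seen. SlASFT was at 5.52 ± 2.04 CPM against 2.64 ± 1.45 CPM (SD, n = 3; log2 fold change 1.12, SE 0.72), and SlGPAT4 at 3.2 ± 1.12 CPM against 1.92 ± 0.549 CPM (log2 fold change 0.76, SE 0.53), with edgeR quasi-likelihood adjusted p of 0.63 and 0.67. SlCD1 and PAL5 had log2 fold changes of -1.86 (SE 0.71) and -1.14 (SE 0.44), with edgeR quasi-likelihood adjusted p of 0.22 and 0.23, and SlGPAT6 had 14 counts against 0 (edgeR quasi-likelihood adjusted p = 0.27). PAL5 turned to 0.28 against the groups that target other genes, and SlCD1, SlGPAT6, SlASFT and SlGPAT4 were at -1.40, 1.77, 0.87 and 0.26 on the log2 scale without passing. In all, 205 genes rose and 320 fell. Solyc05g053060, with 1 count in the control and 2167 in the knockout, had a ratio of 1820 (counting interval 327 to 72000). Solyc01g058673 and Solyc00g090430 were at least 105-fold and 109-fold lower. Against the groups that target other genes Solyc05g053060 stayed higher by 8.37 on the log2 scale, while Solyc01g058673 and Solyc00g090430 were at -7.26 and -7.04 and did not pass. That reference holds the SlMYB41 knockout, in which Solyc01g058673 and Solyc00g090430 also had no count. There Solyc05g053060 was also high, at 33.9 CPM against 0.0529 CPM in the control. The count of genes was 200 with glmTreat, 329 without control library 5, 338 without knockout library 2 and 347 without knockout library 5, and 263 of the 525 changed the same way against the groups that target other genes.

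The SlMYB41 and SlMYB92 knockouts shared 155 genes that were higher and 206 that were lower than in the control. Independent lists would share 5.37 and 7.98. Simulated unchanged groups shared 0 and 0, which was nearly fixed in advance. The covariance was 0.63 against 0.09 simulated and the correlation 0.71 against 0.49, and part of the excess overlap may come from the shared controls. Compared directly, the SlMYB92 knockout had 28 genes higher and 37 lower than the SlMYB41 knockout.

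Overexpression was also compared with knockout of the same gene. SlGPAT4 was higher with SlMYB41 overexpressed than in its knockout by 3.84 on the log2 scale (SE 0.54; edgeR quasi-likelihood adjusted p = 9.3e-05). SlASFT and SlCD1 had log2 differences of 2.50 (SE 0.74) and 2.78 (SE 0.78), with edgeR quasi-likelihood adjusted p of 0.074 and 0.053, both under 0.05 with only the groups compared, and 4 loci passed when adjusted over the list alone. Of these, SlCER6 (log2 difference 2.16, SE 0.91; edgeR quasi-likelihood adjusted p = 0.28) passed only after the list had been shortened. Of all genes, 353 were higher and 232 lower, with a total of 188 with glmTreat and 364 without SlMYB41 overexpression library 3. For SlMYB92, 4 of the 7 loci were higher with overexpression than in the knockout, none lower, and 5 passed when adjusted over the list alone. SlASFT was higher by 4.85 (SE 0.70), SlGPAT4 by 3.82 (SE 0.50), SlCYP86B1 by 4.01 (SE 0.89) and SlCER6 by 3.30 (SE 0.76) on the log2 scale, with edgeR quasi-likelihood adjusted p from 2.9e-05 for SlGPAT4 to 0.0083 for SlCER6. Against a log2 fold change of 1 with glmTreat, SlCER6 did not pass. SlGPAT6 had a log2 difference of 2.42 (SE 0.98; edgeR quasi-likelihood adjusted p = 0.16). Of all genes, 818 were higher and 603 lower. That total was 333 with glmTreat, 933 and 838 without SlMYB92 knockout libraries 2 and 5, and 751 and 797 without SlMYB92 overexpression libraries 2 and 4.

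Against the control, overexpression and knockout of SlMYB41, and of SlMYB92, shared calls in the same direction more than in opposite directions. For SlMYB41, 57 genes were higher and 28 lower in both and 3 moved in opposite directions, and for SlMYB92 these were 53, 35 and 12. Both sets of counts include 20 higher and 6 lower genes that changed the same way in all 7 comparisons with the control. In a chromosome 12 segment that was higher in the control, described below, 6 and 28 genes were called lower in SlMYB41 overexpression and knockout. For SlMYB92 these were 24 and 27, and how many lie in both was not counted. Independent lists would share 3.12 and 1.5 for SlMYB41 and 4.15 and 4.04 for SlMYB92, simulated unchanged groups shared 0, and the covariance was 0.34 and 0.22 against 0.09 simulated. The correlations over all genes, 0.47 and 0.28, did not exceed the 0.49 that chance variation of shared controls alone gave in simulation. Changes in 1 group alone lower a correlation, so this does not decide whether more is shared than such variation gives. SlWRKY71 overexpression shared 48 higher and 17 lower genes with knockout line 4 and 44 and 23 with line 5, with 0 and 3 opposite, but these counts depend on overexpression library 2. Without it, 81 genes were higher, 75 lower and 60 opposite with line 4, where independent lists would share 47.3, 26.6 and 71.5, and 66, 66 and 89 with line 5, where they would share 52.2, 27.3 and 75.8. Simulated unchanged groups shared 0 higher and 0 lower genes with each line, and the covariance was 0.01 and -0.04 against 0.10 simulated. With library 2, independent lists would share 3.68 and 2.08, and 3.99 and 2.48, simulated unchanged groups at most 0.1, and the covariance was 0.08 and 0.05 against 0.10 and 0.09 simulated, with correlations of 0.12 and 0.08 against 0.50 and 0.49. These simulated counts of shared calls, with and without library 2 and for both MYB genes, were nearly fixed in advance. The 3 control libraries cannot be halved, and part of the excess overlap may come from the shared controls.

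With SlWRKY71 overexpressed, none of the 7 loci passed the test against the control, and 2 did when adjusted over the list alone. SlWRKY71 itself rose from 1.57 ± 0.432 to 24.3 ± 18.2 CPM (SD, n = 3), a log2 fold change of 3.96 (SE 0.74; edgeR quasi-likelihood adjusted p = 0.0082). PAL5 was at 261 ± 63.4 CPM against 744 ± 172 CPM (log2 fold change -1.51, SE 0.44; edgeR quasi-likelihood adjusted p = 0.11), and SlCER6 had 21 counts against 2 (edgeR quasi-likelihood adjusted p = 0.13). In all, 88 genes rose and 76 fell. Solyc07g042335 and Solyc04g051513, with no count in the control, were at least 78-fold and 30.9-fold higher. Solyc03g026050 was at least 77.3-fold lower, and Solyc06g033850 had 1 count against 809, a ratio of 812 (counting interval 145 to 32100). Solyc03g026050 was at 9.18 CPM in the control and lower in every other group, with a highest mean of 2.67 CPM in SlWRKY71 knockout line 4. Library 2 of this group stood apart: 1607 genes were called without it, 71 without library 4, 64 without library 5 and 69 without control library 5. The count was 432 with DESeq2, 51 with glmTreat, 29 with only the groups compared and 1809 against the groups that target other genes. SlWRKY71 lost its call without control library 5, without overexpression library 4 and with only the groups compared, with edgeR quasi-likelihood adjusted p of 0.087, 0.064 and 0.11. Against the groups that target other genes 65 of the 164 genes changed the same way, Solyc07g042335 and Solyc04g051513 were higher by 4.6 and 3.44 on the log2 scale, and Solyc03g026050, which was also lost with only the groups compared, and Solyc06g033850 lost their calls, at -3.97 and -3.47 on the log2 scale. PAL5 passed with no filter or with DESeq2, but was at -0.45 with that reference and SlCER6 at 0.41, with edgeR quasi-likelihood adjusted p of 0.47 and 0.71, while SlWRKY71 stayed at 3.82.

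**Figure D3:**
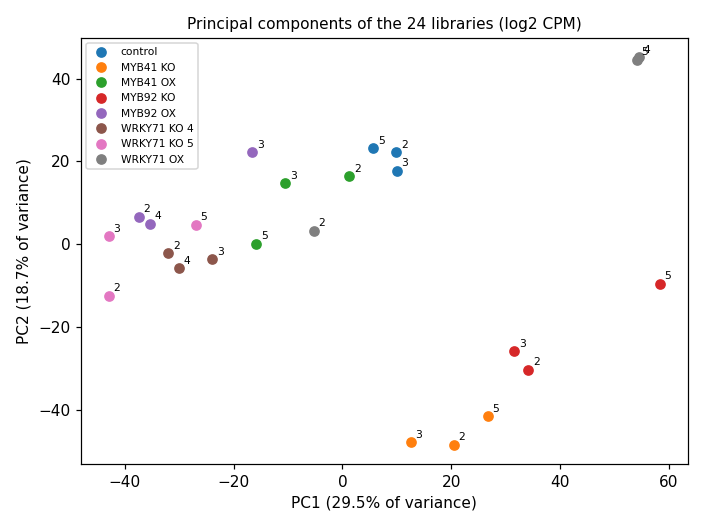
First and second principal components (29.5% and 18.7% of variance) of log2 CPM of the 2000 most variable genes, with 1 dot per library, coloured by group and marked with the library number. SlWRKY71 overexpression libraries 4 and 5 lie together at the upper right, and library 2 lies apart from them, near the middle.

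In SlWRKY71 knockout line 4, PAL5, the entry enzyme of the phenylpropanoid pathway, fell from 744 ± 172 to 254 ± 32.8 CPM (SD, n = 3), a log2 fold change of -1.55 (SE 0.44; edgeR quasi-likelihood adjusted p = 0.037). The other 6 loci did not pass, and 1 passed when adjusted over the list alone. PAL5 lost its call in each of the 6 fits without a library and against the groups that target other genes (log2 fold change -0.49; edgeR quasi-likelihood adjusted p = 0.45), and also with glmTreat. In all, 766 genes rose and 500 fell. Solyc08g008540 was at least 143-fold higher, Solyc08g044345 had a ratio of 288 (counting interval 98.1 to 1400), and Solyc00g500191 had 2 counts against 1976, a ratio of 948 (counting interval 262 to 7830). Solyc01g096470 was at least 100-fold lower. Against the groups that target other genes Solyc08g008540 turned to a log2 fold change of -0.10 and Solyc08g044345 was higher by only 0.64; both are among 26 genes that differed from the control in all 7 comparisons. Solyc00g500191 and Solyc01g096470 stayed at -6.93 and -7.96 there without passing (edgeR quasi-likelihood adjusted p of 0.097 and 0.066), and did not pass with glmTreat either. Leaving out knockout library 2 or 4 ended the call of Solyc00g500191, and leaving out any library but control library 2 that of Solyc01g096470. The count of genes was 2100 with DESeq2, 70 with glmTreat, 411 without control library 3, 249 without control library 5, 406 without knockout library 2 and 222 without knockout library 4, and 355 of the 1266 genes changed the same way against the groups that target other genes.

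In SlWRKY71 knockout line 5, SlGPAT6 and SlCER6 rose, none of the 7 loci fell, and 4 passed when adjusted over the list alone. SlGPAT6, at 0 counts in the control, was at least 11.5-fold higher (edgeR quasi-likelihood adjusted p = 0.032). SlCER6 had 17 counts against 2, a ratio of 12.3 (counting interval 2.91 to 109; edgeR quasi-likelihood adjusted p = 0.045). Both lost their calls against the groups that target other genes, with log2 fold changes of 2.41 and 0.53 and edgeR quasi-likelihood adjusted p of 0.1 and 0.64, and SlCER6 also in each of the 6 fits without a library and SlGPAT6 in 5 of them, all but the fit without knockout library 5. With glmTreat neither passed, and SlCER6 was also lost with no filter. SlCYP86B1 had 25 counts against 5 (log2 fold change 2.66, SE 1.04), and PAL5 was at 284 ± 152 CPM against 744 ± 172 CPM (log2 fold change -1.39, SE 0.44), with edgeR quasi-likelihood adjusted p of 0.11 and 0.054. In all, 829 genes rose and 596 fell. Solyc09g091630 and Solyc07g056180 were at least 90.9-fold and 41.3-fold higher, and Solyc01g096470 and Solyc09g064273 at least 72.6-fold and 47.1-fold lower. Against the groups that target other genes Solyc09g064273 had a log2 fold change of 0.00, Solyc01g096470 stayed at -7.96 without passing (edgeR quasi-likelihood adjusted p = 0.075), and Solyc09g091630 and Solyc07g056180 stayed higher by 8.01 and 4.56. Solyc09g064273 had no count in line 5 or in any group of that reference, and was also lost with DESeq2. Solyc01g096470 was also lost with glmTreat and without any library but control library 2. PAL5 passed with no filter or with DESeq2, but was at -0.33 with the groups that target other genes as reference and SlCYP86B1 at 0.49, with edgeR quasi-likelihood adjusted p of 0.62 and 0.71. The count of genes was 113 with glmTreat, 863 with only the groups compared, 549 without control library 3, 455 without control library 5, 541 without knockout library 3 and 745 without knockout library 5, and 511 of the 1425 genes changed the same way against the groups that target other genes.

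Lines 4 and 5 shared 475 genes that were higher and 297 that were lower than in the control, where independent lists would share 34.7 and 16.3. Simulated unchanged groups shared 0 and 0, which was nearly fixed in advance. The covariance was 0.65 against 0.10 simulated and the correlation 0.82 against 0.49, and part of the excess overlap may come from the shared controls. Compared directly, none of the 7 loci passed, also when adjusted over the list alone, and of all genes 5 were higher and 5 lower in line 5 (629 genes at an unadjusted p under 0.05). The count of 10 was 26 with DESeq2, 21 with no filter, 4 with only the groups compared and 6 without knockout line 5 library 5.

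SlWRKY71 overexpression was compared with both knockout lines together. SlGPAT6 was at 0 counts with overexpression and 31 in the knockouts, at least 6.28-fold lower, and SlCYP86B1 had 1 count against 37, a ratio of 22.5 (counting interval 3.79 to 912). Their edgeR quasi-likelihood adjusted p were 0.029 and 0.022, and both calls were lost without overexpression library 4, overexpression library 5 or knockout line 4 library 3, and with glmTreat. The other 5 loci did not pass, and 2 passed when adjusted over the list alone. SlWRKY71 was higher by 3.59 on the log2 scale (SE 0.57; edgeR quasi-likelihood adjusted p = 0.00039). Of all genes, 3270 were higher and 2382 lower with overexpression, 652 in total with glmTreat, 3621 with only the groups compared, 2440 without overexpression library 4, 2871 without library 5, and 7334 without library 2.

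**Figure D4:**
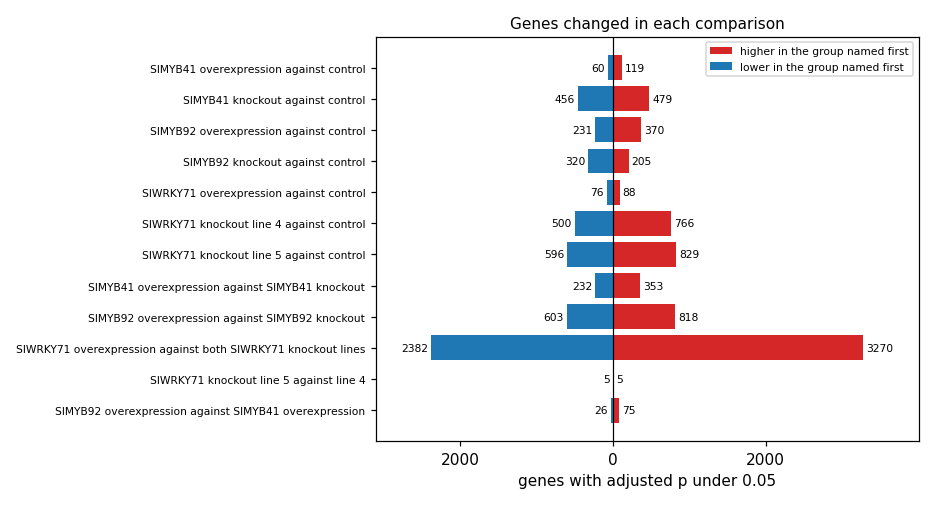
Number of genes with an adjusted p under 0.05 in each of the 12 comparisons, drawn to the right where higher and to the left where lower in the group named first. The bars run from 5 and 5 genes between the SlWRKY71 knockout lines to 3270 and 2382 genes between SlWRKY71 overexpression and the knockout lines.

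Part of every comparison with the control lay in the control itself. There were 26 genes that changed the same way in all 7 comparisons, 20 higher and 6 lower than in the control, among them Solyc08g008540, Solyc08g044345 and Solyc06g033850. Each overlap of calls against the control given above over all libraries includes these 26 genes. Genes from Solyc12g056740 to Solyc12g096760 on chromosome 12, 173 of them expressed, were higher in the control than in the other groups by a median of 0.54 on the log2 scale (95% bootstrap interval over these genes 0.50 to 0.59). Of the 248 genes tested there, 2.42% in SlMYB41 overexpression to 22.2% in each SlWRKY71 knockout line were called lower than in the control, against 0.299% and, in lines 4 and 5, 2.47% and 3% of genes elsewhere. Without this segment and the 26 genes, 147 genes remained for SlMYB41 overexpression, 878 for its knockout, 548 for SlMYB92 overexpression, 469 for its knockout, 126 for SlWRKY71 overexpression, and 1182 and 1339 for its knockout lines 4 and 5.

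**Figure D5:**
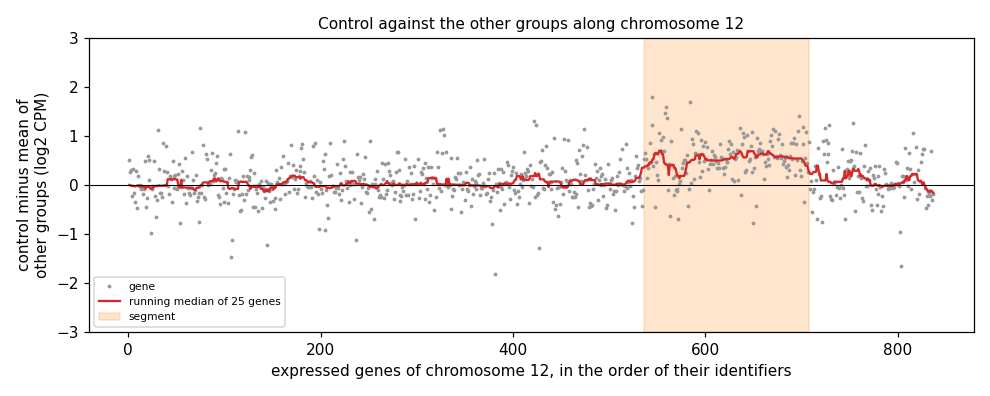
Control minus the mean of the other groups in log2 CPM, for the 837 expressed genes of chromosome 12 in the order of their identifiers (dots), with a running median of 25 genes (line) and the segment shaded. The median over the 173 genes of the segment is 0.54.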

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

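The comparison between the SlWRKY71 knockout lines was planned, and the tests over other splits of the libraries were chosen only after the counts had been seen. The same contrast in both lines against the control differed between lines 5 and 4 for 10 genes by a test of the difference itself. Solyc09g091630 was higher in line 5 by 5.58 (SE 0.80; 189 counts against 5) and Solyc12g010950 by 4.35 (SE 0.64; 151 counts against 10) on the log2 scale, with edgeR quasi-likelihood adjusted p of 0.0075 and 0.0064. Solyc09g089570 was at least 14.5-fold lower in line 5, with a fitted log2 difference of -7.35, and Solyc09g015085 had 2 counts in line 5 against 196, with a fitted log2 difference of -6.04. Their edgeR quasi-likelihood adjusted p were 0.022 and 0.0036. Over the alternatives these adjusted p reached 0.11, 0.072, 0.23 and 0.065 in the order of naming. With the number in the column as block, all of them lost their calls (edgeR quasi-likelihood adjusted p of 0.11, 0.072, 0.11 and 0.056). The count of 10 was 6 without knockout line 5 library 5, 5 with that block and 4 with only the groups compared. Solyc09g015085 was at 8.68 CPM in line 4 and 5.49 CPM in the control. In every other group it was at most 0.387 CPM, so line 4 and not line 5 stood apart from the other constructs.

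Splits of the 3 libraries of a group and the 3 it was compared with number 10, too few for a share under 0.05. The real split gave 179 genes for SlMYB41 overexpression, 935 for its knockout, 601 for SlMYB92 overexpression, 525 for its knockout and 1425 for SlWRKY71 knockout line 5 against the control, and the highest other split gave 0 in each of these. The same held for the 585 genes between SlMYB41 overexpression and knockout, the 1421 between SlMYB92 overexpression and knockout, the 10 between the SlWRKY71 knockout lines and the 101 between SlMYB92 and SlMYB41 overexpression. For SlWRKY71 knockout line 4, the real split gave 1266 genes and the highest other split 1, and in each comparison named so far 1 split, the real one, gave as many genes. For SlWRKY71 overexpression against the control, 2 of the 10 splits gave as many genes, the real one with 164 and another with 600, several times the real count, which points to a structure of the samples. For SlWRKY71 overexpression against both knockout lines, 1 of the 84 splits, the real one with 5652 genes, gave as many, the highest other gave 3058, which argues against a random choice among these libraries.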

How the results depend on the processing

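The alternatives were planned before the data were examined, except the replicate block by column number, the other reference, and the counts without the chromosome 12 segment and shared genes; the shuffling of column numbers and the overlaps without an SlWRKY71 overexpression library were also added later. RLE scaling, a stricter filter and a robust fit left every count of genes within 1.5 times and every call of the 105 named gene results that they tested, and RLE moved the median of all genes by at most 0.02 on the log2 scale. Over 1530 other fits of named genes, 1388 left the call, 114 ended it, 15 gave one and 13 changed sign, counting a value of 0.00 as a change. Where no cause is named, the cause was not tested.

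Counts that moved by over 1.5 times were these. DESeq2 called 342 genes for SlMYB41 overexpression, 1453 for its knockout, 963 for SlMYB92 overexpression, 432 for SlWRKY71 overexpression, 2100 for SlWRKY71 knockout line 4, 26 between the SlWRKY71 knockout lines and 237 between SlMYB92 and SlMYB41 overexpression. The test against a log2 fold change of 1, which asks for larger changes by construction, called 68 and 232 for SlMYB41 overexpression and knockout, 139 and 200 for SlMYB92, 51, 70 and 113 for SlWRKY71 overexpression and lines 4 and 5, 188, 333 and 652 between overexpression and knockout of SlMYB41, SlMYB92 and SlWRKY71, and 24 between SlMYB92 and SlMYB41 overexpression. Fitting only the groups compared gave 29 for SlWRKY71 overexpression, 863 for line 5, 3621 for overexpression against both lines and 4 between the lines, and no filter gave 21 between the lines. Against the groups that target other genes, 119 were called for SlMYB41 overexpression, 556 for its knockout and 1809 for SlWRKY71 overexpression.

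Without 1 library at a time, the counts ran from 94 to 135 for SlMYB41 overexpression, 482 to 876 for its knockout, 261 to 428 for SlMYB92 overexpression, 329 to 471 for its knockout, 64 to 1607 for SlWRKY71 overexpression, 222 to 1489 for line 4 and 455 to 1071 for line 5. Between groups they ran from 364 to 469 for SlMYB41, 751 to 1238 for SlMYB92, 2440 to 7334 for SlWRKY71, 6 to 10 between its lines and 34 to 71 between SlMYB92 and SlMYB41 overexpression. Fewer libraries leave less power.

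The planned replicate block by the labels' numbers was not run, since the columns do not carry them. With the number in the column as block, the count was 379 for SlMYB92 overexpression, 565 for SlWRKY71 knockout line 4, 5 between its lines and 62 between SlMYB92 and SlMYB41 overexpression, and the other 8 counts stayed within 1.5 times. Among named genes this block ended 7 calls and gave 2. PAL5 in line 4 and SlCER6 in line 5 lost theirs (edgeR quasi-likelihood adjusted p of 0.1 and 0.052). PAL5 in line 5 and SlASFT between SlMYB41 overexpression and knockout gained one (edgeR quasi-likelihood adjusted p of 0.047 and 0.035). The data do not settle whether the column numbers pair libraries: deviations from the group means correlated with a median of -0.025 over 67 pairs with the same number (29 over 0.1) and 0.0049 over 185 pairs with different numbers, while 12 of 24 libraries correlated best with their own number, against a mean of 6.57 over 2000 shuffles of the numbers within groups (share with as many 0.043). The latter is a hint from the data, not the design. The planned list tests were not run, for lack of members.

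Changes of sign were as follows. With the other reference, the log2 fold change of SlGPAT6 with SlMYB41 overexpressed was -0.27, of SlMYB41 in its knockout -1.0, of PAL5 with SlMYB92 overexpressed 0.92 and in the SlMYB92 knockout 0.28, and of Solyc08g008540 in SlWRKY71 knockout line 4 -0.10. The value of 0.00 for Solyc09g064273 in line 5 shows no reversal, since that gene had no count there or in that reference. None of the first 4 was called against the control. Without 1 library at a time, uncalled values crossed 0: SlMYB41 in its knockout ran from -1.82 to 2.74, SlASFT there from -0.81 to 0.01, SlMYB92 in its knockout from -2.50 to 2.79, and SlWRKY71 from -0.01 to 0.74 in line 4 and -0.72 to 0.84 in line 5. Of these, SlMYB41 and SlMYB92 had at most 3 counts in either group, so that depth limits them.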

Other observations

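All tests of explanations in this part were chosen only after the patterns had been seen. The first pattern is the segment of chromosome 12 between Solyc12g056740 and Solyc12g096760. Its score of 23 compares with a highest of 12.4 for the best segments of other chromosomes or groups, 12 of which also reached p = 0.01, the smallest that 99 permutations can give, with medians of up to 0.63 in size, so that the score and not the p sets it apart. Normalization or depth is argued against by the rest of the chromosome, where the highest median log2 difference from a group was 0.07. A single deviating library is argued against by the lowest control library, at 0.50 over the segment, above the highest other library at 0.09. An extra copy of the segment in the control line may account for it, as the median of 0.54 lies near the log2 of 3 over 2, 0.58. The interval of 0.50 to 0.59 holds that value. However, it resamples genes of a segment chosen by its score and leaves out the spread between libraries. It is thus no test of an extra copy, and no DNA was analysed here.

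The second pattern is a set of genes on or off in both the SlMYB41 and the SlMYB92 knockout. Taking on as a mean of at least 1 CPM and off as below 0.2 CPM, 41 genes set this pair apart from the other groups, while the next highest of the other 27 pairs had 3. Of the 133 genes over 8-fold changed the same way in both, 23 pairs were neighbours, against a highest of 10 in 2000 permutations. A genetic background shared by the lines could give this. The permutations drew genes at random, so neighbours that change together for another reason are not covered, and this is no test of that background. The same count was 3 for the SlWRKY71 knockout lines and 1 for SlMYB41 and SlMYB92 overexpression, against permuted means of 0.55 and 0.2 and highest of 4 and 3. A single line under both labels is argued against by the 65 genes that differ between the knockouts, where the SlWRKY71 knockout lines differ in 10. Loss of either MYB factor stays open. The median change of these genes, signed as in the knockouts, was 0.21 in SlMYB92 overexpression with quartiles of -0.27 and 1.87. This value cannot decide the question, since 59 of the genes were higher in the knockouts. Of the 133 genes, 22 had no count in the control and could not fall below it. The SlWRKY71 groups, which target neither MYB gene, gave medians of 0.37 with overexpression and 0.40 and 0.21 in knockout lines 4 and 5.

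The third pattern is SlWRKY71 overexpression library 2. The changes of libraries 4 and 5 had a median size of 3.8% in it, with 53.4% of 1587 genes moved the same way (called in a fit that keeps library 2 as a group of its own, where leaving it out gave 1607), and SlWRKY71 was at 5.21 CPM, below the highest library outside the group at 5.55 CPM. A control library under the wrong label is argued against by its median of -0.05 over the chromosome 12 segment, where the lowest control library is at 0.50. Of the 24 genes off in both MYB knockouts it detects 24, with at least 1 count each, where the MYB knockout libraries detect at most 10. These genes were picked by low means in both knockouts and high means in every other group, the one that holds library 2 included. The counts argue against a MYB knockout library, but only weakly, since the choice of genes favours this outcome. Weaker expression of the transgene could account for it, at the 3.8% given above, but cannot be told apart from another origin of the sample, because only 1 library is affected.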
